A study of Mus musculus with 35 samples.

How the data were processed

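Messenger RNA of sorted mouse dendritic cells was measured in 35 libraries of 12 groups. Per the labels' protocols, RNA was extracted with a Qiagen RNA Plus Mini kit, and TruSeq libraries of polyadenylated RNA were made from 100 ng of total RNA. Single-end reads of 86 bases were taken on an Illumina NextSeq instrument, per the submitters' processing notes. The values used are the deposited integer counts of reads per gene, which were made with featureCounts against GRCm38 (mm10), per the submitters' processing notes. The aligner, the versions, the strand setting and the treatment of reads that match several places are not given in the sources used here. The table holds 27179 genes by Entrez number, and every library column was matched to its label. Symbols were added from the RefSeq table of GRCm38.p6 for 25275 genes, and the 1904 without a symbol held 1.38% of the counts. Nothing else was done to the counts before the tests.

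Library totals ran from 13.2 M to 71.4 M counts, with a median of 26.6 M, and 6317 genes had 0 counts in all libraries. At the smallest total 1 count is a level of under 0.1 CPM, and levels below 1 CPM rest on few reads. No library was a copy of another of its group: the smallest chi-square per degree of freedom between a pair was 9.85 (cDC2 Flt3L+IL-4, replicates 2 and 3).

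Libraries were grouped by sorted fraction, IL-4 and stroma as the labels give them. For the group with n = 2 the labels and the design text differ: the text gives 2 replicates to cDC2 from Flt3L+IL-4+OP9DL-1, while the labels give 2 to cDC1, and the labels were followed. The design was written before the data were examined. It has 25 comparisons: IL-4 in each fraction and stroma setting, cDC1 against cDC2 in each culture, OP9 against no stroma and OP9DL-1 against OP9 in each fraction with and without IL-4, and 5 differences between IL-4 effects. The 3 batches are the 3 stroma settings, so comparisons of stroma carry the batch with them.

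Genes were tested with edgeR 4.0.16 in R 4.3.3. The filter filterByExpr by group left 15135 genes. Normalization was TMM, and 1 quasi-likelihood fit of the 12 group means with 23 residual degrees of freedom served all comparisons (glmQLFit and glmQLFTest). The common dispersion was 0.0285, a biological coefficient of variation of 16.9%. A gene was called at a Benjamini-Hochberg false discovery rate under 0.05 within its comparison. Log-CPM values used a prior count of 2. Comparisons that share a group share its chance deviations.

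Genes are named by a rule fixed in the design: the 10 highest and 10 lowest log2 fold changes of a comparison (5 and 5 for differences between effects and for comparisons with IL-4 on both sides) among called genes that separate the libraries of both groups completely and reach 5 CPM in the higher group, without unnamed, immunoglobulin and T cell receptor genes, up to 4 called members of each list, and 13 genes that are always reported (Xcr1, Irf8, Irf4, Sirpa, Batf3, Il4ra, Ccl17, Aldh1a2, Hes1, Dtx1, Esam, Dll1 and Flt3). The text names a part of these. Separation was not asked of differences between effects. For a group at 0 counts, the fold is a bound from 3 counts over the group, and for 1 to 3 counts it is a ratio with a 95% counting interval. Both use counts pooled over the libraries of each group, in which deeper libraries weigh more.

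The 25 gene lists were written from general knowledge before the tests: markers of cDC1, cDC2, plasmacytoid dendritic cells, monocytes and macrophages, neutrophils, mast cells with basophils and eosinophils, B cells, T, NK and innate lymphoid cells, erythroid cells and stromal cells, and genes of the IL-4 and STAT6 response, Notch targets, maturation, MHC class II, MHC class I, interferon stimulation, cell cycle, cholesterol synthesis, glycolysis and hypoxia, Toll-like receptors, C-type lectins with Fc receptors, chemokines with receptors, cytokines, complement and immediate-early stress. Of the listed symbols 2 matched no gene (Hbb-bt and Ahsp). Lists were tested with camera of limma 3.58.1 on voom values with the correlation between genes estimated per list, adjusted over the 25 lists of a comparison. Camera with a preset correlation of 0.01 and fry were run beside it.

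The labels name the animal of each library, so the mouse numbers pair the samples within a batch. As a check, deviations from group means were correlated: libraries of the same mouse and batch had a median r of 0.08 (-0.11 to 0.35, 21 of 51 pairs over 0.1), and libraries of different mice of a batch -0.05 (6 of 102 over 0.1). Across batches the values were 0.05 (43 of 136) for the same number and -0.02 (15 of 272) for different numbers. Whether a number means the same animal in all batches is not given in the sources used here. The fit without a block is reported, and a fit with the mouse as a block was run beside it. For comparisons within a batch and differences of IL-4 effects the block was the mouse within its batch. For comparisons of stroma settings it was the mouse number across batches, a pairing that is not established, so calls gained there are not counted as calls.

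Alternatives were DESeq2 1.42.0, RLE normalization, no filter on low counts, thinning to the smallest library, a fit of only the groups compared, the mouse block, and leaving out each library in turn. After the data were seen, 1 more was added, without the libraries of mouse 1 from Flt3L+IL-4+OP9, and it was applied to the bound below as well. The share of XCR1-negative RNA in XCR1-positive libraries was bounded from genes of at least 20 CPM in cDC2 of the same culture, as the 10th lowest ratio of cDC1 to cDC2 level. Ratios between the fractions used genes of at least 5 CPM.

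The scripts were tested on simulated data drawn from the means and library sizes of IL-4 in cDC1 without stroma over 15135 genes, with 50 genes changed at each fold. There edgeR recovered 19 at 1.5-fold, 41 at 2-fold, 48 at 4-fold and 50 at 8-fold, with 3 false among 161 calls (1.9%). DESeq2 recovered 24, 43, 49 and 50, with 9 false among 175 calls (5.1%). Camera called the raised list of 20 genes and 0 of 20 unchanged lists. In simulated libraries of cDC1 and cDC2 with Flt3L and no stroma, 8% of mixed RNA gave a bound of 9.04%, and unmixed RNA gave 1.36%. These were drawn from pooled group profiles with counting noise only. Spread between mice was not simulated, so the bound in the real libraries is not tested by this. Splicing, alleles and reads outside genes were not analysed here.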

Results

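Conventional dendritic cells, which take up antigen and present it to T cells, were grown from the bone marrow of female C57BL/6 mice for 7 days with 100 ng/ml of Flt3L, the ligand of the receptor tyrosine kinase Flt3 that drives dendritic cell development. The cultures had no stroma, OP9 cells (a mouse bone-marrow stromal line) or OP9DL-1 cells (OP9 cells made to express the Notch ligand Delta-like 1), each with and without interleukin-4 (IL-4). By flow cytometry each culture was sorted into cells with and without XCR1 on their surface, the receptor for the chemokine XCL1 that marks the cDC1 lineage. The XCR1-positive cells are called cDC1 and the XCR1-negative cells cDC2 here, as in the labels. Polyadenylated RNA was sequenced as single-end reads of 86 bases. The 35 libraries fall into 12 groups, of which 11 have n = 3 and cDC1 from Flt3L+IL-4+OP9DL-1 has n = 2. Library totals ran from 13.2 M to 71.4 M counted reads (M for megareads), with a median of 26.6 M. The labels give 3 batches with 3 mice each, and each batch holds the cultures of 1 stroma setting. Effects of IL-4 and differences between cell types were therefore measured within a batch, whereas stroma and batch cannot be told apart. Genes were compared with edgeR over 15135 genes at a false discovery rate of 0.05, and levels are counts per 1 M of the library size after TMM scaling (CPM), as mean ± SD of a group or for 1 library. Log2 differences are given ± SE. The SE is the absolute difference over the square root of its quasi-likelihood F statistic, and so is approximate. Counts of list members are over all genes tested, and a count adjusted over the list alone is added where it differed. List p values are adjusted camera p values with an estimated correlation between genes. Intervals and floors cover counting error only. Folds from 0 to 3 counts use counts pooled over the libraries of a group, so such a bound can exceed the printed mean over the floor. Genes that overlap another gene on the opposite strand are uncertain, since the strand setting of the counting is not given in the sources used here, as are close paralogs such as Sirpb1a and Sirpb1c.

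The first principal component of the 12 groups held 37.2% of the variance and the second 14.9%. Xcr1 (Entrez 23832, GRCm38 chromosome 9: 123852315-123862029) lay between 521 and 1870 CPM in the cDC1 libraries and between 1.42 and 32.1 CPM in the cDC2 libraries, so no library was out of place by this gene. Sirpa, an inhibitory receptor of cDC2, and Irf4, a transcription factor of cDC2, were lower in cDC1 in all 6 cultures.

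**Figure D1:**
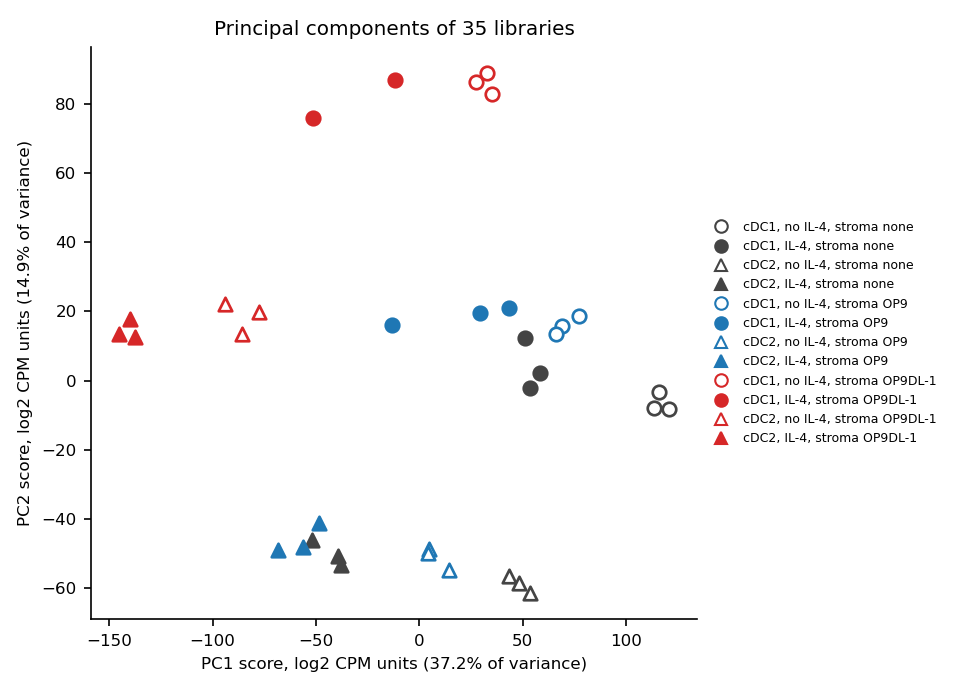
Principal components 1 (x axis, 37.2% of the variance) and 2 (y axis, 14.9%) of log2 CPM, 1 point per library, with circles for cDC1, triangles for cDC2, filled symbols for cultures with IL-4, grey for no stroma, blue for OP9 and red for OP9DL-1. The 35 points show where libraries of the 12 groups lie relative to each other.

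The question in the cultures with Flt3L alone was how far the XCR1-positive and XCR1-negative cells differ and whether stroma and the Notch ligand change that. Without stroma, Xcr1 stood at 550 ± 28.5 CPM in cDC1 and 26.9 ± 4.98 in cDC2 (n = 3 each, 4.36 ± 0.49, adjusted p = 6.8e-08). Since the cells were sorted on XCR1, the direction for Xcr1 was set by the sort in every culture, and its test only checks the labels. Ildr1 (5.89 against 0.284 CPM), Ttc39a (30.1 against 1.48) and Cd81, a tetraspanin (143 against 11.9), were also higher in cDC1. Cd33, a sialic-acid-binding receptor, was at 0.855 ± 0.285 CPM in cDC1 and 83.7 ± 12.1 in cDC2 (-6.62 ± 0.42, adjusted p = 2.3e-12), and Ccr6, a chemokine receptor, was at 0.129 against 9.41 CPM. Of the 15135 genes 2167 were higher and 2574 lower in cDC1. The cDC1 markers were higher for 19 of 20 genes (adjusted p = 0.036), the cDC2 markers lower for 16 of 20 and 17 adjusted over the list alone (0.0026), and the monocyte and macrophage markers lower for 19 of 21 and 20 adjusted over the list alone (0.0077). C-type lectins and Fc receptors were lower in cDC1 for 19 of 25 genes and higher for 3 (0.0077), led by Clec10a (-6.18 ± 0.38) and Mgl2 (-6.05 ± 0.43). The complement genes were lower for 7 of 12 and 8 adjusted over the list alone (0.097), with C3 at -5.71 ± 0.64, and the cytokines lower for 7 of 21 and higher for 2 (0.22), with the interleukin-1 antagonist Il1rn at -9.80 ± 1.24. The B cell markers were lower for 5 of 8 and higher for 1 (0.15), and the erythroid markers lower for 6 of 7 (0.15).

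With OP9, Xcr1 stood at 1010 ± 106 CPM in cDC1 and 26.0 ± 0.931 in cDC2 (n = 3 each, 5.27 ± 0.51, adjusted p = 4.1e-09). Naalad2 (Entrez 72560), a peptidase, was at 15.8 against 0.134 CPM, the orphan receptor Gpr141b (Entrez 319293) at 66.8 against 0.733, and the mannose-6-phosphate receptor Igf2r at 64.5 against 0.74. Clec10a, a lectin for galactose sugars, was at 10.2 ± 3.62 CPM in cDC1 and 400 ± 33.8 in cDC2 (-5.29 ± 0.35, adjusted p = 5.1e-12), and the fractalkine receptor Cx3cr1 at 6.6 against 245. In all 1990 genes were higher and 2362 lower in cDC1. The cDC1 markers were higher for 19 of 20 and 20 adjusted over the list alone (0.015), the cDC2 markers lower for 16 of 20, and 17 lower with 1 higher adjusted over the list alone (0.0018). The monocyte and macrophage markers were lower for 15 of 21 and 17 adjusted over the list alone (0.011). Lectins and Fc receptors were lower for 19 of 25 and higher for 5 (0.015), among them the Langerhans cell lectin Cd207 at 6.39 ± 1.69. The interferon-stimulated genes were lower for 22 of 30 and higher for 1 (0.10, and 0.022 with mouse as a block), and the IL-4 and STAT6 response genes lower for 18 of 32 and higher for 3, against 21 and 3 adjusted over the list alone (0.11, and 0.049 with the block).

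With OP9DL-1 the fractions lay farther apart by count, with 3485 genes higher and 4157 lower in cDC1. Xcr1 stood at 1400 ± 67 CPM in cDC1 and 4.3 ± 0.83 in cDC2 (n = 3 each, 8.38 ± 0.60, adjusted p = 3.4e-12), Gpr141b at 288 ± 13.5 against 0.231 ± 0.152 (10.57 ± 0.55, adjusted p = 7.9e-15), and the Wnt receptor Fzd1 at 296 against 1.72. Naalad2 had 2 counts over the cDC2 group, a 1580-fold difference with a counting interval of 438 to 13100. The lectin Clec4a4 was at 2.88 ± 0.769 CPM in cDC1 and 150 ± 18.5 in cDC2 (-5.71 ± 0.29, adjusted p = 6.6e-15), and the adhesion molecule Dscam at 0.386 against 39. Irf8, a transcription factor that cDC1 need, was higher in cDC1 by 1.52 ± 0.26 without stroma, 1.87 ± 0.26 with OP9 and 3.96 ± 0.29 with OP9DL-1 (n = 3 each, adjusted p at most 4.6e-05), and the change of that difference with stroma was not tested. All 20 cDC1 markers were higher in cDC1 (adjusted p = 0.048), and the cDC2 markers were lower for 19 of 20 and higher for 1 (0.028). The Notch targets were lower in cDC1 for 15 of 19 and higher for 1 (0.049, and 0.069 with mouse as a block, which ends that call), with Dtx1, a ubiquitin ligase induced by Notch, at -5.65 ± 0.37. The markers of T cells, NK cells and innate lymphoid cells were lower in cDC1 for 19 of 20 (0.18), those of neutrophils for 15 of 15 (0.32), and those of mast cells, basophils and eosinophils for 15 of 19 and 17 adjusted over the list alone (0.32).

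The same comparison in the cultures with IL-4 asks whether the fractions keep apart when the cytokine is present. Without stroma, Ctla2b, a cysteine protease inhibitor with the close paralog Ctla2a, was at 360 ± 94.1 CPM in cDC1 and 3.37 ± 0.113 in cDC2 (n = 3 each, 6.74 ± 0.33, adjusted p = 1.1e-14), and Naalad2 at 15.9 against 0.189. The transcription factors Hoxa10 (0.46 against 6.99 CPM) and Erg (0.672 against 9.05) were lower in cDC1. In all 2688 genes were higher and 3356 lower in cDC1. The markers of plasmacytoid dendritic cells were lower in cDC1 for 14 of 17 (adjusted p = 0.016), with the transcription factor Spib at -3.46 ± 0.41. All 20 cDC1 markers were higher (0.050, and 0.033 with mouse as a block), while the Toll-like receptors were higher for 10 of 16 and lower for 3 (0.17, and 0.033 with the block). With OP9, Xcr1 was at 916 ± 291 against 10.8 ± 11.1 CPM (n = 3 each, 6.46 ± 0.55, adjusted p = 4.6e-10) and Gpr141b at 33.2 ± 19.2 against 0.18 ± 0.185, with 2900 genes higher and 3500 lower. There all 20 cDC1 markers were higher (0.049), and the maturation genes, which dendritic cells induce on activation, were higher in cDC1 for 24 of 26 and lower for 1, with 25 higher adjusted over the list alone (0.19), led by the interleukin-12 subunit Il12b (5.19 ± 0.56) and the chemokine Ccl17 (4.64 ± 0.83). The cell cycle genes were lower in cDC1 for 25 of 28 (0.19). With OP9DL-1, Gpr141b was at 286 ± 107 CPM in cDC1 (n = 2) and 0.146 ± 0.191 in cDC2 (n = 3, 10.76 ± 0.55, adjusted p = 7.0e-15), and 3258 genes were higher and 4080 lower. That count of 7338 fell to 4493 without replicate 2 of the cDC1 group. When only the groups compared were fitted, 2994 were higher and 2602 lower, so the larger part was then higher. All 20 cDC1 markers were higher (0.078). The recombinase gene Rag2 was at 0.444 against 6.61 CPM and the globin Hbb-b1 at 1.64 against 25.9, higher in cDC2. The MHC class II genes were higher in cDC1 in all 3 cultures with IL-4, for 10 of 14 with 1 lower and 11 adjusted over the list alone without stroma (0.21), for 12 with OP9 (0.19) and for 13 with OP9DL-1 (0.18), with H2-Ab1 higher by 1.98 ± 0.21, 2.09 ± 0.21 and 3.59 ± 0.24.

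The effect of IL-4 on cDC2 was asked in each stroma setting. Without stroma, Hpgd (Entrez 15446, chromosome 8: 56294552-56321046), the enzyme that breaks down prostaglandins, fell from 710 ± 125 to 0.157 ± 0.17 CPM (n = 3 each, -12.08 ± 0.74, adjusted p = 3.1e-13). The adhesion receptor Adgre4 fell from 58.6 ± 6.82 to 0.201 ± 0.0846 CPM, the junction protein F11r from 206 ± 14.1 to 1.61 ± 0.338, and the immediate-early transcription factor Egr1 (Entrez 13653, chromosome 18: 34861207-34864956) from 406 ± 40.8 to 3.25 ± 0.619 (-6.97 ± 0.68, adjusted p = 1.4e-09). Eomes (Entrez 13813, chromosome 9: 118478186-118486132), a T-box factor of cytotoxic lymphocytes, rose from 0.0463 ± 0.0411 to 286 ± 32.6 CPM (12.19 ± 0.64, adjusted p = 1.9e-14). Mboat2, a lipid acyltransferase, was at 0 counts without IL-4 and at 23.5 ± 5.75 CPM with it, in pooled counts at least 696-fold higher against 3 counts over the group. Granzyme K (Gzmk) rose at least 463-fold from 0 counts.

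With IL-4 and no stroma, 4439 genes rose and 4002 fell in cDC2, together 55.8% of the genes tested. All 16 Toll-like receptor genes fell (adjusted p = 0.030), with Tlr13 at -3.57 ± 0.26, the coreceptor Cd14 at -3.19 ± 0.34 and Tlr2 at -2.92 ± 0.21. Of the immediate-early genes 16 of 20 fell and 2 rose (0.038), among them Egr3 (-5.38 ± 0.63) and Fos (-4.81 ± 0.51). The monocyte and macrophage markers fell for 18 of 21 and rose for 2 (0.12, and 0.042 with mouse as a block), with the Fc receptor Fcgr1 at -6.38 ± 0.67 and lysozyme Lyz2 at -3.87 ± 0.19. The cell cycle genes rose for 25 of 28 (0.13, and 0.029 with the block), with Tyms at 2.01 ± 0.17. The MHC class II genes fell for 12 of 14 and rose for 1 (0.21), the maturation genes fell for 21 of 26 and rose for 2 (0.35). The interferon-stimulated genes fell for 21 of 30 and rose for 1 (0.21), with Ifit3 at -6.67 ± 0.42 beside its paralog Ifit3b at -6.68 ± 0.51. The chemokines and their receptors fell for 14 of 26 and rose for 4, against 15 and 4 adjusted over the list alone (0.24), with Ccl5 at -5.66 ± 0.46 and Ccl24 (Entrez 56221), an eosinophil attractant, rising by 8.37 ± 0.88. The cytokines fell for 11 of 21 and rose for 3 (0.35), with Il12b at -6.39 ± 0.71, and the complement genes fell for 6 of 12 (0.35). Glycolysis and hypoxia genes rose for 15 of 22 and fell for 1, with 16 rising adjusted over the list alone (0.52), and cholesterol synthesis genes rose for 16 of 21 and fell for 1 (0.35). The MHC class I genes changed for 4 of 16, 1 up and 3 down, and only 1, which fell, adjusted over the list alone (0.92). The IL-4 and STAT6 response genes went both ways, with 13 of 32 rising and 11 falling, 12 falling adjusted over the list alone (0.92). Their median was -0.15, their mean 0.27 and the test upward. The retinal dehydrogenase Aldh1a2 fell by 9.22 ± 1.41 on the log2 scale, while the STAT-induced inhibitor Cish rose by 6.16 ± 0.51.

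Markers of other cells moved in the same libraries. The T, NK and innate lymphoid cell markers rose for 15 of 20 and fell for 1, with 16 rising adjusted over the list alone (0.36), and Nkg7, a granule protein of cytotoxic cells, rose by 10.01 ± 0.77. The mast cell, basophil and eosinophil markers rose for 11 of 19 and fell for 2, with 12 rising adjusted over the list alone (0.59), led by the basophil protease Mcpt8 (11.10 ± 0.86). The plasmacytoid markers rose for 11 of 17 and fell for 1, against 11 and 2 adjusted over the list alone (0.21), with the DNA polymerase Dntt at 8.45 ± 0.63. The neutrophil markers rose for 4 of 15, the granule protein Ctsg (6.28 ± 0.69) among them, and fell for 9. Their median was -1.52, their mean 0.17 and the test downward (0.91). The B cell markers rose for 3 of 8 and fell for 2, with a median of -0.05, a mean of 0.75 and the test upward (0.91). The erythroid markers rose for 2 of 7 and fell for 1, with a median of -0.89, a mean of -0.40 and the test upward (0.87). The cDC2 markers fell for 14 of 20 and rose for 1, with 15 falling adjusted over the list alone (0.13), Cd209a at -5.10 ± 0.45 and Sirpa at -2.28 ± 0.34, and the cDC1 markers fell for 11 of 20 and rose for 3 (0.57).

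With OP9, Hpgd again fell in cDC2 on IL-4, from 721 ± 83.9 to 0.37 ± 0.427 CPM (n = 3 each, -11.20 ± 0.71, adjusted p = 2.0e-12), and Adgre4 from 117 ± 5.74 to 0.0608 ± 0.0282 (-10.93 ± 0.41, adjusted p = 2.9e-17). The lectin Cd209a, one of a family of close paralogs, fell from 283 ± 54.7 to 8.17 ± 5.79 CPM. Ccl24 (chromosome 5: 135569935-135573123) rose from 0.121 ± 0.149 to 200 ± 93.8 CPM (10.68 ± 1.06, adjusted p = 1.2e-08), and Eomes from 0.156 to 38.6. In all 3632 genes rose and 3475 fell. The Toll-like receptors fell for 14 of 16 and 15 adjusted over the list alone (0.020), with Cd14 at -2.89 ± 0.33. The MHC class II genes fell for 11 of 14 (0.19), with H2-Aa at -1.84 ± 0.21, the maturation genes fell for 21 of 26 and rose for 2 (0.28), and the interferon-stimulated genes fell for 22 of 30 and 24 adjusted over the list alone (0.19). The cell cycle genes rose for 26 of 28 (0.19) and the cholesterol synthesis genes for 16 of 21 (0.19). Among other-cell markers, those of T, NK and innate lymphoid cells rose for 12 of 20 and fell for 2 (0.42), and those of mast cells, basophils and eosinophils rose for 11 of 19 and fell for 3 (0.51). Those of neutrophils fell for 8 of 15 and rose for 4 (0.81), with the granule protein Ngp going from 90.7 ± 64.3 to 2.61 ± 0.931 CPM. In replicate 1 of cDC2 with IL-4 and OP9, Irf8 was at 186 and Xcr1 at 1.42 CPM. Both genes were called lower with IL-4 (-0.68 ± 0.26 and -1.32 ± 0.46). Neither call held without that library (-0.32 and -0.79) or when only the groups compared were fitted (-0.67, adjusted p = 0.19, and -1.31, 0.14). The Irf8 call also ended without cDC2 Flt3L+IL-4+OP9 replicate 3 (-0.58) and without cDC2 Flt3L+OP9 replicate 1 (-0.61), and the Xcr1 call without cDC2 Flt3L+IL-4+OP9 replicate 3 (-1.14).

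With OP9DL-1, Ccl24 rose in cDC2 from 1.69 ± 1.13 to 101 ± 16.2 CPM (n = 3 each, 5.86 ± 0.74, adjusted p = 6.0e-07). The lectin Mgl2 rose from 4.09 ± 1.03 to 122 ± 13.3 (4.92 ± 0.36, adjusted p = 3.5e-11), the mast cell protease Cma1 from 0.502 ± 0.64 to 45.4 ± 13.5, and Hey1, a Notch-induced repressor, from 0.23 to 17.3. Hpgd fell from 43.8 ± 8.76 to 0.46 ± 0.139 CPM (-6.53 ± 0.59, adjusted p = 1.5e-09), Il12b from 62.7 to 3.26, the inhibitory receptor Cd22 from 174 to 9.21 and Sirpb1a from 94.4 to 2.1. Dtx1 fell by 1.87 ± 0.30 on the log2 scale and Esam, an adhesion molecule of cDC2, by 2.67 ± 0.52. In all 3142 genes rose and 2848 fell. All 14 MHC class II genes fell (adjusted p = 0.22, and 0.027 with mouse as a block), with the class II activator Ciita at -2.35 ± 0.19. The Toll-like receptors fell for 10 of 16 and rose for 2 (0.26, and 0.027 with the block), the maturation genes fell for 19 of 26 and rose for 1 (0.31), and the interferon-stimulated genes fell for 18 of 30 and 19 adjusted over the list alone (0.26). The cell cycle genes rose for 4 of 28 and 1 adjusted over the list alone (0.92). In the same libraries the neutrophil markers rose for 14 of 15 (0.26), the mast cell, basophil and eosinophil markers for 14 of 19 with 1 falling (0.26), and the T, NK and innate lymphoid cell markers for 12 of 20 with 1 falling, 13 rising adjusted over the list alone (0.31). The neutrophil protease Ctsg rose by 3.51 ± 0.56 and the high-affinity IgE receptor chain Fcer1a by 4.40 ± 0.48.

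**Figure D2:**
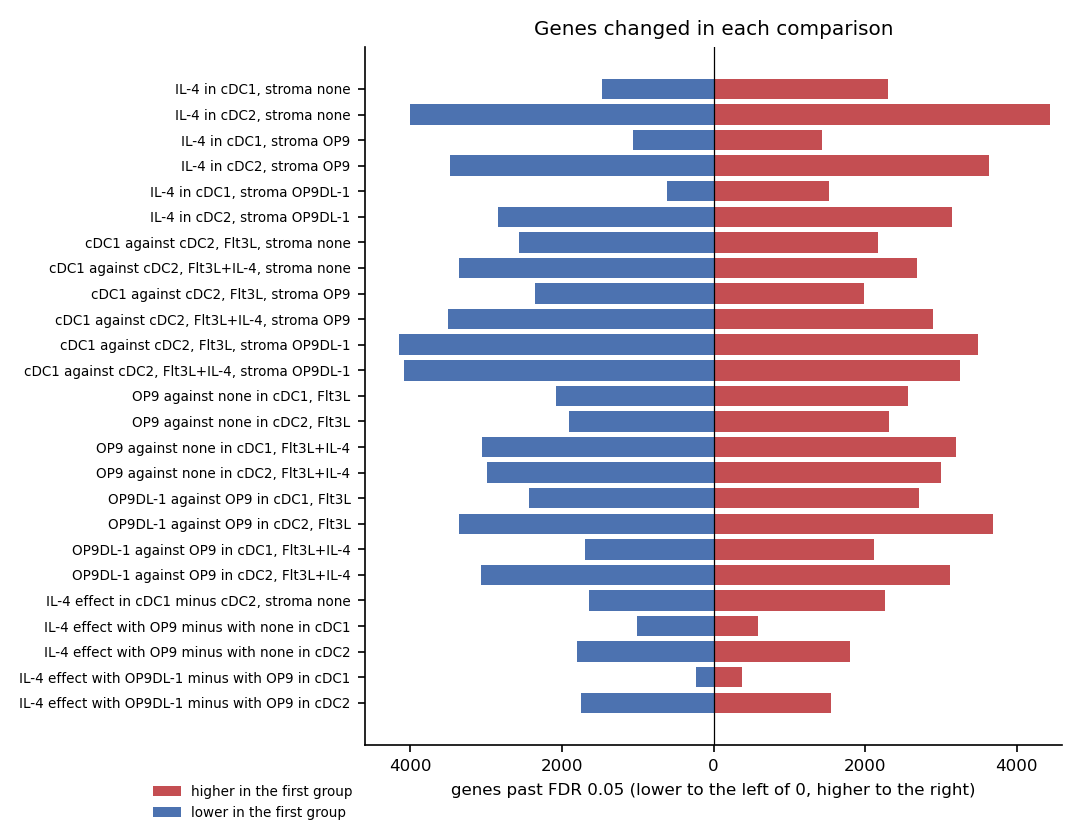
Number of genes past a false discovery rate of 0.05 in each of the 25 comparisons (x axis, genes), with genes lower in the first group to the left of 0 and genes higher to the right. IL-4 moved 8441, 7107 and 5990 genes in cDC2 and 3776, 2495 and 2141 in cDC1, in the order no stroma, OP9 and OP9DL-1.

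In cDC1 the question was the same. Without stroma, Ccl24 was at 0 counts over the group without IL-4 and at 12.3 ± 8.02 CPM with it, in pooled counts at least 307-fold higher against 3 counts over the group. The same bound was 561-fold for the basophil protease Prss34 (23.6 ± 7.07 CPM), 332-fold for Ctsg (14.8 ± 3.83) and 296-fold for the mast cell protease Cpa3 (12.2 ± 3.48). Mgl2 rose by 6.63 ± 0.44 (n = 3 each, adjusted p = 1.4e-11) and Cd8a, the CD8 alpha chain found on some cDC1, by 3.32 ± 0.48 (6.9e-06). The Cd8a level was low, at 0.402 to 0.76 CPM without and 5.42 to 7.14 with IL-4. In cDC1 with OP9DL-1 it lay lower with IL-4, at 233 and 473 CPM against 875 to 908 without. Hpgd fell from 92.9 ± 49.4 to 1.55 ± 1.11 CPM (-5.88 ± 0.52, adjusted p = 2.8e-09), the collagen Col4a2 from 29.3 to 0.383, Cd209a from 83.8 ± 3.68 to 1.96 ± 0.922, F11r from 136 to 4.25 and Egr1 from 298 to 18.7. The Notch target Hes1 fell by 3.71 ± 0.50. In all 2299 genes rose and 1477 fell. The cell cycle genes rose for 25 of 28 (adjusted p = 0.27, and 0.035 with mouse as a block), and the immediate-early genes fell for 9 of 20, against 11 falling and 1 rising adjusted over the list alone (0.070, and 0.035 with the block). The glycolysis and hypoxia genes rose for 17 of 22 and 18 adjusted over the list alone (0.61), with Vegfa, a growth factor for blood vessels, at 4.15 ± 0.50, and the IL-4 and STAT6 response genes rose for 17 of 32 and fell for 3 (0.61). The stromal markers fell for 15 of 22 and rose for 2, with 16 falling adjusted over the list alone (0.61), in a culture without stroma. Col1a1 was at 24.3 CPM in replicate 1 of cDC1 with Flt3L alone, and at 1.76 and 5.67 in replicates 2 and 3. With IL-4 it was at 0.148, 0.0172 and 2.39 CPM, so the fall was largest against that 1 library. The mast cell, basophil and eosinophil markers rose for 11 of 19 and fell for 1, against 14 and 1 adjusted over the list alone (0.70). The T, NK and innate lymphoid cell markers rose for 9 of 20 (0.70), and the neutrophil markers for 6 of 15 and 9 adjusted over the list alone (0.70).

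With OP9, Plet1, a surface protein of some antigen-presenting cells, rose in cDC1 from 0.397 ± 0.129 to 170 ± 130 CPM (n = 3 each, 8.69 ± 1.09, adjusted p = 2.2e-06), and the VEGF receptor Flt1 from 0.0574 to 5.73. Ccl24 rose from 1 count over the group to 93.6, 8.46 and 23 CPM in replicates 1 to 3. Ccl17 rose by 3.97 ± 0.77 and the IL-4 receptor chain Il4ra by 1.33 ± 0.26. Hpgd fell from 40.5 ± 8.46 to 0.185 ± 0.281 CPM (-7.65 ± 0.74, adjusted p = 3.2e-08), the lectin Cd209e from 21.6 to 0.126 and the claudin Cldn1 from 155 to 18.2. In all 1429 genes rose and 1066 fell. That count of 2495 was 960 (662 up and 298 down) when only the groups compared were fitted, 1426 without replicate 2 of cDC1 with OP9 and no IL-4, and 1567 without replicate 1 of cDC1 with OP9 and IL-4. The last library stood apart, with Sirpa at 144 and Il4ra at 401 CPM. Sirpa and Irf4 were called higher with IL-4 (1.37 ± 0.34 and 1.21 ± 0.28), and neither call held without it (0.75 and 0.74) or when only the groups compared were fitted (1.37 and 1.22). The Sirpa call also ended without replicate 2 of cDC1 with OP9 and no IL-4 (1.08). The cholesterol synthesis genes rose for 19 of 21 (adjusted p = 0.041), with Hmgcs1 at 1.09 ± 0.13 and Lss at 0.99 ± 0.11, and the glycolysis and hypoxia genes for 18 of 22 and 22 adjusted over the list alone (0.19). The IL-4 and STAT6 response genes rose for 17 of 32 and fell for 1, against 19 and 2 adjusted over the list alone (0.26). The mast cell, basophil and eosinophil markers rose for 12 of 19 and fell for 1, against 13 and 1 adjusted over the list alone (0.67), and the T, NK and innate lymphoid cell markers for 11 of 20 and 16 adjusted over the list alone (0.67).

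With OP9DL-1 the largest rises by this rule were in genes of granulocytes. Epx (Entrez 13861), the eosinophil peroxidase, rose in cDC1 from 0.887 ± 0.345 CPM (n = 3) to 287 ± 257 (n = 2, 8.28 ± 0.68, adjusted p = 1.2e-08), and Prg2 (Entrez 19074), the eosinophil major basic protein, from 11.1 ± 5.89 to 1270 ± 1090 (6.82 ± 0.68, adjusted p = 5.2e-08). Ccl24 (0.161 to 14.5 CPM) and Mgl2 (0.597 to 40.5) rose here as well. Hpgd fell from 185 ± 38.7 to 6.74 ± 6.41 CPM (-4.72 ± 0.57, adjusted p = 9.0e-07), the protease inhibitor Serpinb2 from 51.7 to 1.98 and the nuclear receptor Pparg from 8.9 to 0.859. In all 1522 genes rose and 619 fell. Without replicate 1 of the IL-4 group the count of 2141 was 776, of which 660 rose and 116 fell. The mast cell, basophil and eosinophil markers rose for 17 of 19 (adjusted p = 0.039), those of neutrophils for all 15 (0.068, and 0.021 with mouse as a block), and those of T, NK and innate lymphoid cells for 17 of 20 and 18 adjusted over the list alone (0.058, and 0.013 with the block). The monocyte and macrophage markers rose for 11 of 21 and fell for 1, against 13 and 2 adjusted over the list alone (0.11). None of the 16 MHC class I genes was called by edgeR, and the cholesterol synthesis genes fell for 4 of 21 and rose for 1 (0.35). Xcr1 was not called in the IL-4 comparison of cDC1 in any stroma setting (0.68 ± 0.43, -0.13 ± 0.43 and 0.24 ± 0.47). When only the groups compared were fitted, it was called higher with IL-4 without stroma (0.67, adjusted p = 0.01). Il4ra, higher with IL-4 in cDC1 with OP9, was not called in cDC1 without stroma (0.14 ± 0.26) or with OP9DL-1 (0.35 ± 0.29). In cDC2 it was lower with IL-4 without stroma (-0.97 ± 0.26, adjusted p = 0.0024) and with OP9DL-1 (-1.13 ± 0.26, 0.001). With OP9 it was not called in cDC2 (0.14 ± 0.26).

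**Figure D3:**
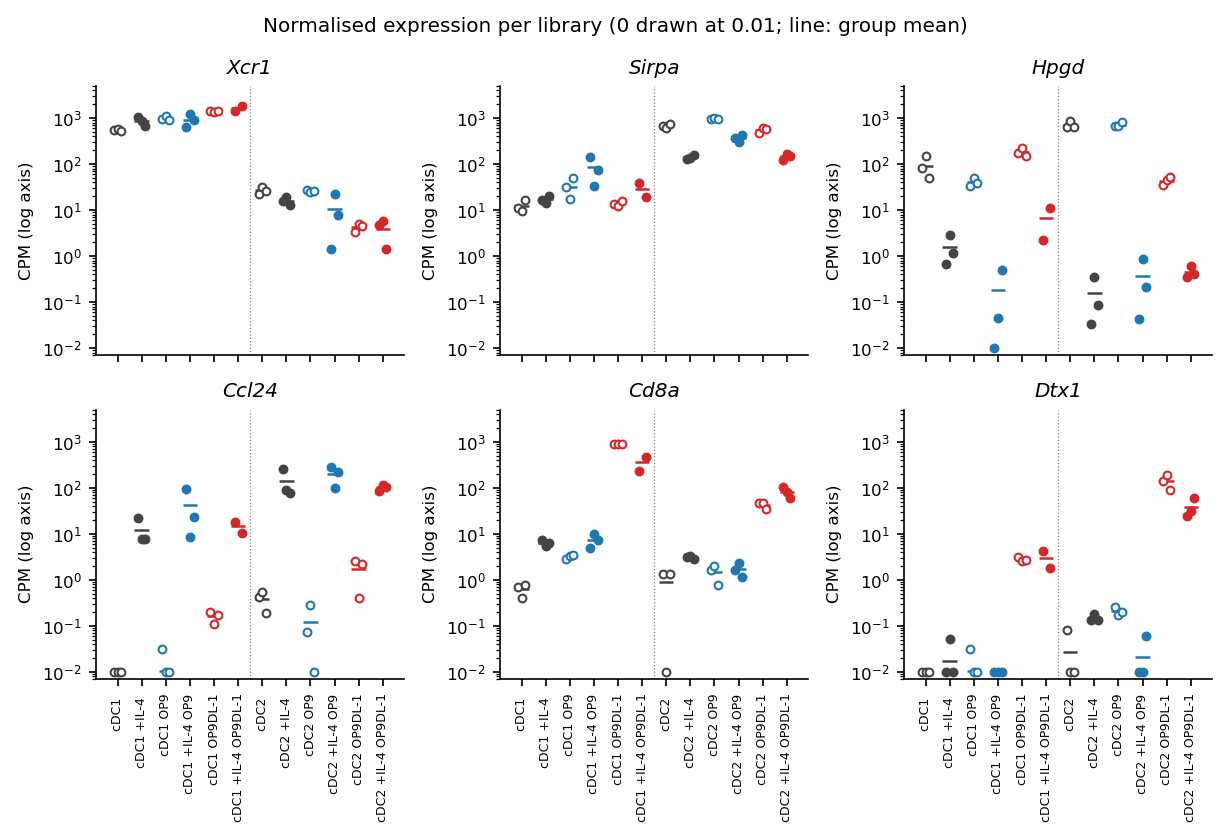
Level of Xcr1, Sirpa, Hpgd, Ccl24, Cd8a and Dtx1 in the 12 groups, 1 point per library (y axis, CPM on a log scale, with 0 drawn at 0.01) and a line at the group mean. Hpgd is lower with IL-4 in each fraction and stroma setting, as from 710 to 0.157 CPM in cDC2 without stroma, and Dtx1 is high in cDC2 with OP9DL-1.

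As a bound on RNA of XCR1-negative cells in each XCR1-positive library, the level of genes abundant in cDC2 of the same culture (at least 20 CPM) was divided by their cDC2 level, and the 10th lowest ratio was taken. It lay between 0.89% and 3.5% in the 9 libraries without IL-4 and between 6.74% and 27.5% in the 8 with IL-4, the highest in replicate 1 of Flt3L+IL-4+OP9. The bound is the largest share the lowest genes allow, not a measured share. Ccl24, which rose with IL-4 in cDC1 in each stroma setting, was higher in cDC2 of each of these cultures. Without stroma it was at 21.6, 7.7 and 7.64 CPM in cDC1 and 253, 90.1 and 77.6 in cDC2 (replicates 1 to 3). The bound in those cDC1 libraries was 6.78%, 7.85% and 10.34%. For Ccl24, RNA of XCR1-negative cells and a rise in cDC1 were thus not told apart. In Flt3L+IL-4+OP9DL-1 the level in cDC1 was between 23% and 36% of that in cDC2 for most of the mast cell, basophil and eosinophil markers, while Prg2 (1270 against 159 CPM) and Epx (287 against 25.9) were higher in cDC1.

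**Figure D4:**
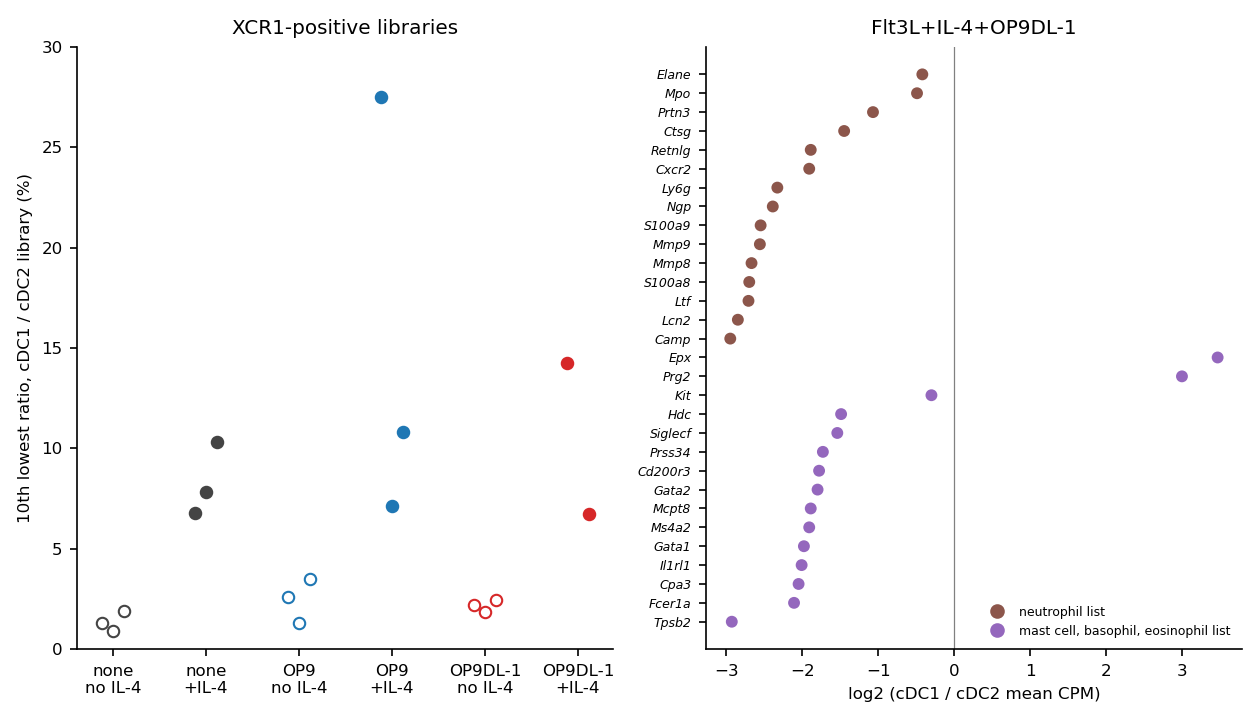
Left, the 10th lowest ratio of cDC1 to cDC2 level among genes of at least 20 CPM in cDC2 (y axis, %), 1 point per XCR1-positive library by culture, from 0.89 to 3.5 without IL-4 and 6.74 to 27.5 with it. Right, log2 of the cDC1 over cDC2 mean CPM of each neutrophil and mast cell, basophil and eosinophil marker in Flt3L+IL-4+OP9DL-1, with an SD of 0.84 and 1.85.

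Whether IL-4 acted on cDC1 and cDC2 alike was tested as a difference of effects, within the cultures without stroma. It differed for 3908 genes, 2261 with the effect higher in cDC1 and 1647 with it lower. The effect is a signed log2 fold change, so a higher effect can be a smaller fall as well as a larger rise. The Toll-like receptor list went from 5.38 to 5.75 log2 CPM without IL-4 to 3.6 to 3.71 with it in cDC2. In cDC1 it lay at 4.39 to 4.71 without and 4.49 to 4.56 with IL-4, so its difference reflects the fall in cDC2. The effect of IL-4 was higher in cDC1 for 15 of 16 Toll-like receptor genes and 16 adjusted over the list alone (adjusted p = 0.011), with a median difference of 1.99 and Tlr13 at 3.70 ± 0.34 (n = 3 per group, adjusted p = 3.4e-08). It was higher in cDC1 for 11 of 14 MHC class II genes and 12 adjusted over the list alone (0.22), for 21 of 26 maturation genes (0.24), for 19 of 30 interferon-stimulated genes and 20 adjusted over the list alone (0.25), and for 15 of 21 monocyte and macrophage markers (0.11, and 0.026 with mouse as a block). The guanylate-binding protein Gbp2 (6.47 ± 0.93) was among these, and Hes1 (-4.81 ± 0.72) and 21 of 28 cell cycle genes, 22 adjusted over the list alone (0.22), had the lower effect in cDC1.

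Genes called with IL-4 overlapped between the fractions. Without stroma 1676 genes rose in both, against 674.3 for independent lists (odds ratio 9.81), and 1026 fell in both, against 390.5 (8.16). With OP9 the shared counts were 777 up (4.53) and 619 down (5.44), and with OP9DL-1 868 up (6.62) and 278 down (3.79). All 18 overlaps tested, between fractions and between stroma settings of a fraction, passed Fisher's exact test, with a largest adjusted p of 4.6e-23. That test takes genes as independent units and does not measure the spread between mice. The fractions come from the same cultures, and RNA of XCR1-negative cells in cDC1 was not taken out of these counts. Some calls went opposite ways. Without stroma 99 genes rose in cDC1 and fell in cDC2, and 34 did the reverse. Of genes that fell in cDC1 without stroma, 142 fell with OP9DL-1 and 116 rose. Log2 fold changes of the fractions correlated across genes at r = 0.62, 0.58 and 0.53 in the order no stroma, OP9 and OP9DL-1, where genes are not independent replicates.

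Whether the effect of IL-4 depended on stroma was tested in each fraction, a comparison in which an additive shift between batches cancels. With OP9 against none the effect differed in cDC1 for 1600 genes (584 higher, 1016 lower) and in cDC2 for 3602 (1803 higher, 1799 lower). The count in cDC1 was 691 when only the groups compared were fitted, 1001 without replicate 2 of cDC1 with OP9 and no IL-4, and 1033 without replicate 2 of cDC1 with Flt3L alone. That in cDC2 was 2328 without replicate 3 of cDC2 with OP9 and no IL-4 and 2397 without replicate 2 of cDC2 with Flt3L alone. Egr1 had the higher effect with OP9 in cDC1 (5.52 ± 0.77, n = 3 per group, adjusted p = 6.8e-05) and in cDC2 (6.88 ± 0.82, 4.6e-06). Without stroma Egr1 fell 14.6-fold in cDC1 and 124-fold in cDC2 with IL-4. On the log2 scale the difference of effects exceeds that fall in cDC1 and nearly equals it in cDC2. The estimates with OP9 were thus a rise in cDC1 and little change in cDC2. Without IL-4, Egr1 in cDC2 was already 11.8-fold lower with OP9 than without stroma, where stroma and batch cannot be told apart. The immediate-early genes were higher for 10 of 20 in cDC1, against 12 higher and 2 lower adjusted over the list alone (adjusted p = 0.013, median 1.09), and in cDC2 for 10 with 1 lower, against 11 and 2 adjusted over the list alone (0.036, median 1.36, and 0.052 with mouse as a block, which ends that call). Socs3, a brake on cytokine signalling, was at 4.36 ± 0.73 in cDC1. The cell cycle genes had the lower effect with OP9 in cDC1 for 25 of 28 (0.050, and 0.028 with the block). In cDC2 Nrarp, a feedback inhibitor of Notch, was lower by 4.90 ± 0.72, and the T, NK and innate lymphoid cell markers were lower for 8 of 20 and higher for 1 (0.85).

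With OP9DL-1 against OP9 the effect of IL-4 differed in cDC1 for 602 genes (373 higher, 229 lower) and in cDC2 for 3310 (1555 higher, 1755 lower). The count in cDC1 was 344 when only the groups compared were fitted and 278 without replicate 1 of cDC1 with IL-4 and OP9DL-1. In cDC1 the cholesterol synthesis genes had the lower effect with OP9DL-1 for 17 of 21 and 19 adjusted over the list alone (adjusted p = 0.0044, median -1.02), with Lss at -1.41 ± 0.17 (adjusted p = 4.0e-06), and in cDC2 for 13 of 21 and 19 adjusted over the list alone (0.23). Adgre4 had the higher effect in cDC2 by 8.82 ± 0.50 and lysozyme Lyz2 by 5.70 ± 0.26 in cDC2 and 3.68 ± 0.26 in cDC1. Adgre4 fell 2090-fold in cDC2 with OP9, so its higher effect marks a smaller fall with OP9DL-1. The neutrophil markers had the higher effect for 6 of 15 in cDC1 and 12 adjusted over the list alone (0.14), and for 9 of 15 in cDC2 (0.24), with the granule protein Ngp at 6.06 ± 0.87 and 7.45 ± 0.88. The class II activator Ciita was lower by 2.01 ± 0.25 in cDC2.

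**Figure D5:**
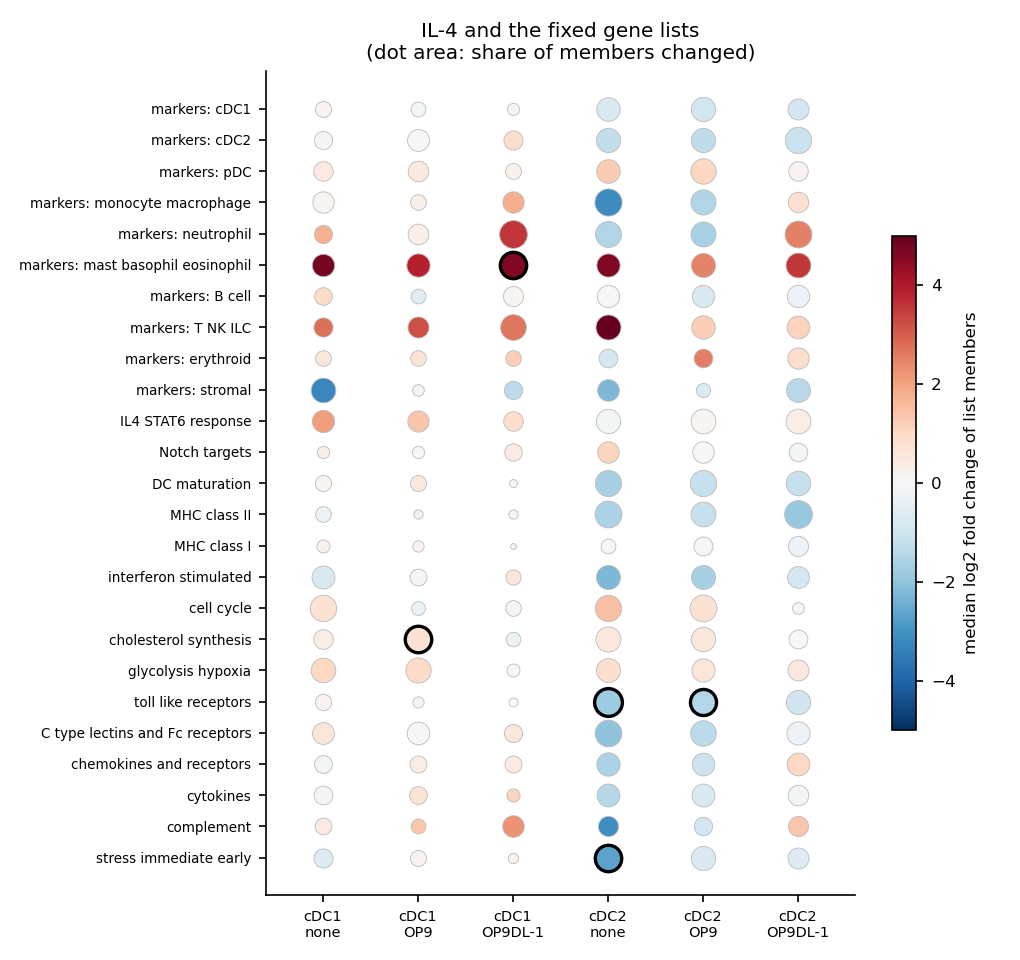
Share of changed genes (dot area) and median log2 fold change (colour, clipped at 5 either way) of 25 gene lists (y axis) in the 6 IL-4 comparisons (x axis), with a black ring where the adjusted camera p with an estimated correlation is under 0.05. Rings mark Toll-like receptors in cDC2 without stroma (0.030) and with OP9 (0.020), immediate-early genes in cDC2 without stroma (0.038), cholesterol synthesis in cDC1 with OP9 (0.041) and mast cell, basophil and eosinophil markers in cDC1 with OP9DL-1 (0.039).

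OP9 cultures were compared with cultures without stroma for each fraction, with and without IL-4. Since each stroma setting is its own batch, stroma and batch cannot be told apart in these 4 comparisons. RNA of OP9 cells in the sorted fractions was not told apart from expression by the sorted cells, for genes such as H19, Cxcl12, Bgn and Col3a1. Col1a1 was at 25, 16.1 and 21.1 CPM in cDC1 with Flt3L and OP9, and at 24.3, 1.76 and 5.67 without stroma (replicates 1 to 3). With Flt3L alone, H19 (Entrez 14955, a long noncoding RNA) was at 0 counts in cDC1 without stroma and 27.4 ± 15.8 CPM with OP9, in pooled counts at least 705-fold higher against 3 counts over the group (n = 3 each). Mpo, the granule peroxidase of neutrophils, was at 0.235 ± 0.156 and 130 ± 43.9 CPM (9.20 ± 0.89, adjusted p = 1.1e-08), and the Notch ligand Jag1 at 0.118 and 9.14. Spint1 (Entrez 20732), a protease inhibitor, was lower with OP9 at 13.1 ± 2.95 against 486 ± 45.8 CPM (-5.20 ± 0.52, adjusted p = 1.8e-08), as were Ctla2b at 9.08 against 507, Ly6a at 28.8 against 797 and Ahrr, the repressor of the aryl hydrocarbon receptor, at 3.08 against 96.8. Hes1 was lower by 3.39 ± 0.53. In all 2573 genes were higher and 2085 lower. The maturation genes were higher for 19 of 26 and lower for 1, with 20 higher adjusted over the list alone (adjusted p = 0.57). The glycolysis and hypoxia genes were higher for 14 of 22 and 16 adjusted over the list alone (0.68). So were the cholesterol synthesis genes for 11 of 21 and 13 adjusted over the list alone (0.74), and the neutrophil markers for 8 of 15 and 10 adjusted over the list alone (0.74). The stromal markers were higher for 12 of 22 and lower for 3, against 12 and 4 adjusted over the list alone (0.74), with the chemokine Cxcl12 at 4.53 ± 0.69.

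In cDC2 with Flt3L alone, Spint1 was at 0.892 ± 0.452 CPM with OP9 against 185 ± 39 without (n = 3 each, -7.72 ± 0.65, adjusted p = 1.6e-09). The purine receptor P2rx5 was at 0.637 against 34.8, the kinase Dapk2 at 1.03 against 43.2 and Egr1 at 29.1 ± 21.9 against 406 ± 40.8. Cxcl12 was higher at 8.85 ± 3.17 against 0.112 ± 0.106 CPM (6.24 ± 0.83, adjusted p = 2.9e-06), the matrix protein Bgn at 9.99 against 0.332 and the neutrophil elastase Elane at 39.4 against 0.683. In all 2311 genes were higher and 1910 lower. The immediate-early genes were lower for 12 of 20 and higher for 1, with 13 lower adjusted over the list alone (adjusted p = 0.018). Cholesterol synthesis genes were higher for 18 of 21 and 19 adjusted over the list alone (0.30), glycolysis and hypoxia genes for 17 of 22 and 18 adjusted over the list alone (0.55), and stromal markers for 13 of 22 and 17 adjusted over the list alone (0.55).

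With IL-4, 3203 genes were higher and 3055 lower with OP9 in cDC1, and 3008 higher and 2993 lower in cDC2. In cDC1 Il12b was at 129 ± 91.9 against 1.3 ± 0.89 CPM (n = 3 each, 6.64 ± 0.60, adjusted p = 6.2e-09). The collagen Col3a1, a stromal product, was at 13.5 ± 2.5 CPM against 1 count over the group, a 2010-fold difference with a counting interval of 360 to 79500. Ctla2b was at 4.5 against 360 CPM and Ahrr at 1.4 against 85.2. The maturation genes were higher for 23 of 26 and lower for 2 (adjusted p = 0.29), the cell cycle genes lower for 21 of 28 and 24 adjusted over the list alone (0.29). The cholesterol synthesis genes were higher for 16 of 21 (0.29), the glycolysis and hypoxia genes higher for 17 of 22 (0.34), and the stromal markers higher for 18 of 22 (0.29). In cDC2 Nrarp was at 4.73 ± 1.16 against 121 ± 27.5 CPM (n = 3 each, -4.65 ± 0.36, adjusted p = 6.3e-10), the apolipoprotein Apol7c at 11.3 against 186 and the mast cell protease Mcpt4 at 8.77 against 0.092. There the interferon-stimulated genes were higher for 20 of 30 and lower for 2, with 22 higher adjusted over the list alone (0.58). The cholesterol synthesis genes were higher for 18 of 21 (0.20), the glycolysis and hypoxia genes for 15 of 22 (0.53), and the stromal markers for 15 of 22 with 1 lower (0.58).

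OP9DL-1 stroma, which carries the Notch ligand DL-1, was compared with OP9, again with stroma and batch inseparable. In cDC1 with Flt3L alone, Cd8a (Entrez 12525), the CD8 alpha chain of lymphoid cDC1, was at 892 ± 16.5 against 3.18 ± 0.288 CPM (n = 3 each, 8.14 ± 0.44, adjusted p = 5e-14). The DNase Dnase1l3 (Entrez 13421) was at 1230 ± 166 against 7.57 ± 1.37 and the serpin Serpinb2 at 51.7 against 0.0472. The adhesion receptor Adgrl3 went from 0 counts to 15 ± 5.21 CPM, at least 400-fold higher in pooled counts. The chemokine receptor Ccr2 was at 10.1 ± 2.65 against 1330 ± 70.9 CPM (-7.04 ± 0.31, adjusted p = 2.3e-15), the lectin receptor Klrb1b at 2.93 against 297 and the lectin Cd209a at 0.213 against 38.7. Among the Notch targets, Hes1 was higher by 5.28 ± 0.54, Dtx1 by 7.35 ± 0.83 and Esam by 2.61 ± 0.71. Dtx1 was at 3.1, 2.55 and 2.62 CPM in cDC1 with OP9DL-1 and 139, 191 and 89.5 in cDC2 (replicates 1 to 3). The bound on XCR1-negative RNA in those cDC1 libraries was 2.18%, 1.86% and 2.44%, so Dtx1 RNA of cDC2 was not told apart from a rise in cDC1. Esam there was at 0.799, 0.993 and 0.402 CPM before TMM scaling. Xcr1 (0.48 ± 0.43, adjusted p = 0.41) and Irf8 (0.18 ± 0.26, adjusted p = 0.61) were not called, but Xcr1 was when only the groups compared were fitted (0.46, adjusted p = 0.015). Dll1, which the OP9DL-1 cells were made to express, was higher by 4.32 ± 0.70 (adjusted p = 2.2e-05), while 1 of 22 stromal markers was higher and 1 lower (0.98). In all 2719 genes were higher and 2439 lower. T, NK and innate lymphoid markers were higher for 18 of 20 and lower for 1 (adjusted p = 0.47), and Notch targets higher for 11 of 19 and lower for 3 (0.69). MHC class I genes were higher for 11 of 16 (0.47), and cholesterol synthesis genes for 18 of 21 with 1 lower (0.47). Lectins and Fc receptors were higher for 4 of 25 and lower for 16, with 18 lower adjusted over the list alone (0.47).

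In cDC2 with Flt3L alone the Notch targets were higher for 17 of 19 and 19 adjusted over the list alone (adjusted p = 0.029). Dtx1 (Entrez 14357), a Notch regulator, was at 140 ± 50.7 against 0.209 ± 0.0456 CPM (n = 3 each, 9.31 ± 0.50, adjusted p = 4.3e-13), Hes1 was higher by 7.42 ± 0.72, and Esam, an adhesion molecule of splenic cDC2, by 5.12 ± 0.64. The mast cell protease Mcpt1 (Entrez 17224) went from 0 counts to 35.9 ± 28.3 CPM, at least 980-fold higher in pooled counts, and the granzyme Gzma from 0.102 to 81. The mannose receptor Mrc1 was at 0.166 ± 0.0862 against 142 ± 31.2 CPM (-9.46 ± 0.72, adjusted p = 2.7e-11), the lectins Clec10a at 5.67 against 400 and Cd209a at 4.57 against 283, and Irf8 was lower by 1.91 ± 0.26. Dll1 was higher by 3.66 ± 0.81 (adjusted p = 0.00049), and the stromal markers were higher for 2 of 22 and lower for 2, against 1 and 1 adjusted over the list alone (0.85). In all 3692 genes were higher and 3362 lower. T, NK and innate lymphoid markers were higher for 20 of 20, monocyte and macrophage markers lower for 15 of 21, and lectins and Fc receptors lower for 17 of 25 and higher for 3, each at an adjusted p of 0.12. With replicate numbers paired across batches as a block, these 3 lists were at 0.044, 0.046 and 0.046. That pairing is not established, so these are not counted as calls. The T, NK and innate lymphoid list lay at -0.97 to -0.08 log2 CPM with OP9 and 3.71 to 4.28 with OP9DL-1. Other cells among the XCR1-negative cells and a change within cDC2 were not told apart here. This holds for Mcpt1, Gzma and the Notch targets as well. Maturation genes were higher for 21 of 26, with 22 higher and 1 lower adjusted over the list alone (0.43), and interferon-stimulated genes for 21 of 30 (0.43). MHC class I genes were higher for 14 of 16 and lower for 2 (0.43), and cell cycle genes higher for 14 of 28 and 15 adjusted over the list alone (0.43). The cDC1 markers were lower for 14 of 20 and higher for 4 (0.43). Glycolysis and hypoxia genes were lower for 14 of 22 and higher for 1 (0.43).

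With IL-4, Mcpt1 was in cDC1 at 0 counts with OP9 and 98.2 ± 34.4 CPM with OP9DL-1 (n = 3 and n = 2, at least 1650-fold), and in cDC2 at 0.116 ± 0.134 and 583 ± 190 (n = 3 each, 12.67 ± 0.93, adjusted p = 2.1e-08). The neutrophil granule peptide Camp was higher with OP9DL-1, from 0.117 ± 0.103 to 321 ± 66.8 CPM in cDC2 (11.43 ± 0.75, adjusted p = 5.3e-12) and from 0.0677 to 41.4 in cDC1. The metalloprotease Adamdec1 went in cDC2 from 0 counts to 89.4 ± 15.9 CPM, at least 2240-fold in pooled counts. Mrc1 was at 2.4 against 327 CPM in cDC2, and Ccr2 at 49.2 ± 24.8 against 1520 ± 550 in cDC1 (-4.95 ± 0.34, adjusted p = 3e-11). Hes1 was higher by 5.58 ± 0.67 in cDC1 and 3.96 ± 0.51 in cDC2. Dll1 was higher by 5.78 ± 1.11 in cDC1 (adjusted p = 3e-04) and 5.65 ± 0.94 in cDC2 (2.5e-05). The stromal markers were higher for 1 of 22 and lower for 5 in cDC1, with 6 lower adjusted over the list alone (0.76), and higher for 2 and lower for 9 in cDC2 (0.96). In cDC1 2115 genes were higher and 1697 lower, 3812 in all, against 1560 when only the groups compared were fitted and 2165 without cDC1 Flt3L+IL-4+OP9DL-1 replicate 2. In cDC2 3118 were higher and 3073 lower. The Notch targets were higher for 10 of 19 in cDC1 (adjusted p = 0.31) and for 16 in cDC2, with 17 adjusted over the list alone (0.050, and 0.025 with the same block, which is not counted here either). T, NK and innate lymphoid markers were higher for 19 of 20 and lower for 1 in cDC1 (0.31) and higher for 17 in cDC2 (0.10, 0.025 with the block). Mast cell, basophil and eosinophil markers were higher for 15 of 19 and lower for 1 in cDC1, with 16 higher adjusted over the list alone (0.31), and higher for 17 in cDC2 (0.17, 0.043 with the block). Neutrophil markers were higher for 10 of 15 in both (0.31 and 0.20). Other cells in the sorted fractions and a change within cDC1 or cDC2 were not told apart for these markers either. In cDC2 interferon-stimulated genes were higher for 26 of 30 and lower for 2, against 26 and 3 adjusted over the list alone (0.20), cholesterol synthesis genes lower for 19 of 21 (0.20), and MHC class II genes lower for 12 of 14 and higher for 1 (0.25).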

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

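The tests of this part were set in the design. The differences between IL-4 effects were tested as such, by a contrast of effects within the same fit. Their splits are printed but decide nothing, which was seen only after they were run. A split exchanges libraries with and without IL-4, so the effect of IL-4 itself enters the spread of the groups. Few genes are then left in most splits whether or not the effects differ, and chance is neither excluded nor supported by these counts.

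Without stroma the effect of IL-4 differed between cDC1 and cDC2 for 3908 genes, and the median difference over the Toll-like receptor genes was 1.99 on the log2 scale. Of 25 splits of the same libraries, 2 gave as many genes, the real one included. The real split gave 4148 genes in that fit and the highest other 5640, from a split that exchanged all 3 libraries of 1 pair of groups and 1 of the other.

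The effect of IL-4 in cDC1 differed between OP9 and no stroma for 1600 genes, and in cDC2 for 3602 genes. Only the real 1 of 25 splits gave as many in each (691 against a highest other of 32 in cDC1, and 3721 against 2826 in cDC2, in fits of the groups compared). The median difference over the immediate-early genes was 1.09 in cDC1 and 1.36 in cDC2.

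Between OP9DL-1 and OP9 the effect of IL-4 differed for 3310 genes in cDC2, where 1 of 25 splits, the real one, gave as many (2898 against 911). In cDC1 it differed for 602 genes, with a median of -1.02 over the cholesterol synthesis genes. That comparison has a group with n = 2 and was not split. Stroma settings are batches. An additive shift between batches cancels in these differences of effects, while stroma and a batch that changes the effect of IL-4 itself cannot be told apart.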

How the results depend on the processing

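Of the alternatives, leaving out both Flt3L+IL-4+OP9 libraries of mouse 1 was chosen after the data were seen. With DESeq2, RLE normalization, no filter, thinning to the smallest library (13.2 M counts) or the replicate block, all 25 counts of genes stayed within 1.5 times, and under no alternative did a call reverse among the 698 single-gene results. Of those, 110 changed side of the threshold under at least 1 alternative, and all alternatives planned were run. Fitting only the groups compared gave 960 genes in place of 2495 for IL-4 in cDC1 with OP9 (69.0% higher, a shift of 11.7 points), 1560 in place of 3812 for OP9DL-1 against OP9 in cDC1 with IL-4, 691 in place of 1600 for the difference of IL-4 effects between OP9 and no stroma in cDC1, and 344 in place of 602 for that between OP9DL-1 and OP9 in cDC1. For cDC1 against cDC2 with IL-4 and OP9DL-1 it gave 2994 higher and 2602 lower (53.5% higher, a shift of 9.1 points) in place of 3258 and 4080, which turned the larger part from lower to higher, and it moved the median log2 fold change by 0.102. Leaving out both libraries of mouse 1 gave 1605 for IL-4 in cDC1 with OP9, and its other 10 counts stayed within 1.5 times.

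Leaving out 1 library at a time gave 1426 to 2715 genes for IL-4 in cDC1 with OP9 (lowest without cDC1 Flt3L+OP9 replicate 2, and 1567 without cDC1 Flt3L+IL-4+OP9 replicate 1), and 776 to 2016 for IL-4 in cDC1 with OP9DL-1 (lowest without cDC1 Flt3L+IL-4+OP9DL-1 replicate 1, with 85.1% higher, a shift of 14.0 points). It gave 4493 to 6970 for cDC1 against cDC2 with IL-4 and OP9DL-1, and 2165 to 3673 for OP9DL-1 against OP9 in cDC1 with IL-4, both lowest without cDC1 Flt3L+IL-4+OP9DL-1 replicate 2. For the differences of IL-4 effects between OP9 and none it gave 1001 to 1877 in cDC1 (lowest without cDC1 Flt3L+OP9 replicate 2, and 1033 without cDC1 Flt3L replicate 2) and 2328 to 3647 in cDC2 (lowest without cDC2 Flt3L+OP9 replicate 3, and 2397 without cDC2 Flt3L replicate 2). Between OP9DL-1 and OP9 in cDC1 it gave 278 to 732 (lowest without cDC1 Flt3L+IL-4+OP9DL-1 replicate 1). The other 18 counts stayed within 1.5 times. The cause of these shifts was not tested. Of 625 list tests, 24 passed 0.05 with the estimated correlation, 303 with the preset one, 329 with fry, 535 with fry in both directions and 42 with the replicate block, and all 24 passed with the preset one too. The block brought 20 list tests under 0.05 and ended 2 list calls, as given in the results, and changed no other list call. Of the 20, 6 are comparisons of OP9DL-1 with OP9 in cDC2, where the block pairs mouse numbers across batches, which is not established. Among single genes it ended 0 calls and added 6. Among these is Ccl17 for OP9DL-1 against OP9 in cDC2 (2.16, adjusted p = 0.043), which for the same reason is not counted as a call.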

Other observations

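The tests on RNA of XCR1-negative cells, on a lower share of cDC2 and on a single source of granulocyte RNA were chosen after some of the values behind them had been seen, and so was the rule of the bound (10th lowest ratio, 20 CPM). The criterion of the test on the share of cDC2 was widened after its OP9 result was seen. It asks whether the lower quartile of a list lies above the upper quartile of another. It first set the highest against the lowest list, which left OP9 undecided (medians of 2.55 for erythroid cells and -1.64 for neutrophils), and now takes any pair of lists. The explanation by RNA of XCR1-negative cells was narrowed to the proportions of those libraries after its results were seen. The splits were planned.

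Genes rose with IL-4 in the XCR1-positive libraries that are abundant in XCR1-negative cells, and the bound on RNA of such cells was higher with IL-4 (6.74% to 27.5%) than without (0.89% to 3.5%). As the whole cause, such RNA in the proportions of the XCR1-negative libraries was set against the gain of each raised gene. The gain exceeded what the highest bound of the culture brings for 91.8% of 2299 genes without stroma and 89.3% of 1522 with OP9DL-1. With OP9 it did so for 64.8% of 1429, and for 91.1% of 908 without mouse 1 of that culture, where the bound falls to 10.84%. Among markers of mast cells, T or NK cells and neutrophils the part was 61.5% of 26 without stroma and 81.6% of 49 with OP9DL-1. With OP9 it was 22.2% of 27, and 23.1% of 13 without mouse 1. Most of these markers there gained less than the bound allows. The bound was itself taken from the lowest ratios of cDC1 to cDC2 level in the same libraries. Most genes abundant in cDC2 therefore lie at or above the bound of their library by its rule. A high part was thus largely set in advance. In no culture do these parts tell RNA of XCR1-negative cells and a rise in cDC1 apart. RNA of XCR1-negative cells in the proportions of their libraries stays open, as does a response of cDC1 to IL-4. RNA of a subset of XCR1-negative cells in other proportions is not tested by this and stays open too. A purity check of the XCR1-positive sort would separate them.

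With IL-4, 14 of 20 cDC2 markers fell in the XCR1-negative cells in each stroma setting and 1, 1 and 4 rose (none, OP9, OP9DL-1), while the list passed in none (adjusted p = 0.13, 0.13 and 0.26). A lower share of cDC2 with the other cells in unchanged proportions would raise alike the markers of every other type that cDC2 do not carry themselves. The medians of other lists lay apart by 8.16 without stroma (T, NK and innate lymphoid cells against monocytes and macrophages), 4.04 with OP9 (erythroid cells against monocytes and macrophages) and 2.82 with OP9DL-1 (neutrophils against B cells), each with quartiles apart. With Flt3L alone, however, the lower list of each pair was higher in cDC2 than in cDC1 of the same stroma. The monocyte and macrophage list was at 4.18 to 4.7 against 1.28 to 1.95 log2 CPM without stroma, and at 4.59 to 4.74 against 1.94 to 2.37 with OP9. The B cell list was at 2 to 2.06 against 0 to 0.73 with OP9DL-1. The cDC2 may thus carry these lists, so the gaps decide nothing. A lower share of cDC2, a change in the types whose markers rose, and a response of cDC2 to IL-4 all stay open. Surface markers used in the sort beyond XCR1 are not given in the sources used here.

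Granulocyte markers were present in both fractions with IL-4 and OP9DL-1. If 1 source of RNA supplied both, the ratio of cDC1 to cDC2 level would be alike over the markers. For the mast cell, basophil and eosinophil markers the SD of its log2 was 1.85, which argues against a single source of the whole list. It rests on the eosinophil genes Prg2 (2040 and 503 CPM in the 2 cDC1 libraries, 186, 190 and 101 in cDC2) and Epx (469 and 106, against 31.8, 33.9 and 12). Of the 15 markers 11 lay at 23.1% to 35.7% of the cDC2 level, so 1 source for those stays open. For the 15 neutrophil markers the SD was 0.84. Most lay between 12.9% (Camp) and 26.9% (Retnlg) of the cDC2 level, so 1 source for those stays open. Above them were Ctsg at 36.6%, Prtn3 at 47.7%, Mpo at 71.3% and Elane at 74.6%, and for the whole list no value decides it. Granulocytes are a candidate source that a sort on granulocyte surface markers would remove, and genes of dendritic cells under IL-4 are the other.

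For the 17 comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. Every other split also mixes libraries of both groups, so the difference itself enters the spread and these counts decide nothing. In each, 1 of 10 splits gave as many genes, and the highest other gave 0. The real split gave 3245, 8254, 960, 6574 and 4963 genes for IL-4 (cDC1 and cDC2 without stroma, cDC1 and cDC2 with OP9, cDC2 with OP9DL-1). It gave 3654, 6664, 3900, 4899 and 7790 for cDC1 against cDC2 (Flt3L and Flt3L+IL-4 without stroma, the same with OP9, Flt3L with OP9DL-1). For OP9 against none it gave 3731, 3090, 4885 and 6662 (cDC1 and cDC2 with Flt3L, then with IL-4), and for OP9DL-1 against OP9 4796, 7011 and 4963 (cDC1 and cDC2 with Flt3L, cDC2 with IL-4). Comparisons with the group of 2 libraries were not split.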
